A study of Mus musculus with 132 samples.

How the data were processed

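The values are gene counts deposited by the authors, 1 table per cohort and RNA fraction, with 132 libraries in 7 tables. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned to mm10 with STAR 2.5.2b and counted with featureCounts 1.6.0 of the Subread package. Per the labels, whole-cell and visual cortex tables hold exon counts and nuclear and chromatin-associated tables hold gene-body counts. Genotype, fraction, age and sex come from the sample labels, where libraries are stranded total RNA. The strand setting, the treatment of reads that map to several places and the gene annotation used for counting are not stated, so overlapping, antisense and paralogous genes are uncertain. Nothing was removed: every sample matched 1 column, and no 2 libraries of a group held the same counts.

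Counts were fitted in edgeR 4.0.16 (R 4.3.3) with TMM scaling, the filterByExpr filter and the quasi-likelihood test, 1 fit per comparison, and p-values were adjusted by Benjamini and Hochberg over the genes tested, with 0.05 as the limit. DESeq2 1.42.0 served as the second tool, svaseq of sva 3.50.0 gave 2 surrogate variables, and the sex of the Dnmt3a mice was tried as a covariate. Comparisons were each mutant against wild type or control within 1 cohort and fraction, the difference of the genotype effect between chromatin-associated and nuclear RNA, the difference between the 2 MeCP2 alleles within a fraction, and chromatin-associated against nuclear RNA in wild-type mice. Gene-body and exon counts were not subtracted from each other in any fit. Replicate numbers were not taken as pairs, because the labels do not state littermate pairs. After the values were in hand, mice of the same number were compared: R306C and wild-type whole-cell libraries of 1 number correlated at 0.133 or more in all 10 pairs (median 0.402), so for this table a blocked value stands beside the unblocked one where it changes a call or moves a count of calls by over 1.5 times. The other genotype tables had pairs below 0.1, and their blocked counts and list values stand in the closing section. KO and wild-type libraries of 1 number still correlated at medians of 0.337, 0.249 and 0.284 in whole-cell, nuclear and chromatin-associated RNA. Replicate number therefore carries structure shared by both genotypes of the KO cohort. On the second principal component of nuclear RNA, replicates 1 to 3 of both lay at 8.785 or more. Replicates 4 to 10 lay at -0.4636 or less. With this number as a block KO calls were 4561, 3028 and 2946 in the 3 fractions, against 2767, 1748 and 1579 without. Whether the number marks littermates is not stated, so pairing of the KO mice is not excluded. Nuclear and chromatin-associated libraries of 1 number and genotype correlated at a median of 0.362 to 0.568 in the 4 forebrain groups. The lowest pair in wild type of the KO cohort was at -0.16.

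Gene spans were taken from RefSeq (GRCm38.p6) by symbol or synonym, with a span for 24419 of 24500 symbols, and transcript length and GC from GENCODE M21. The long-gene index of a library is the mean log2 CPM of genes over 100 kb minus that of all other genes, compared between genotypes by 100000 permutations and adjusted over 7 comparisons. Gene groups are 36 lists fixed in advance and tested with camera of limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and with the correlation estimated from the libraries, adjusted over the lists of a comparison. A list needed 3 members with enough counts. Members were called over all genes, and again with adjustment over the list alone. Correlations of effects were compared with 100 joint permutations of genotype over mice, and counts of calls with 99 other random splits of the same libraries into groups of the same sizes. Recovery was measured on simulated counts with the real means, depths and dispersions, in which 200 genes carried known fold changes. Recovery of the difference between fractions with the mouse as a block was added after results were seen.

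Genes were named by a rule: Mecp2 and Dnmt3a in each comparison, the 8 largest rises and falls among called genes with mean log2 CPM of at least 1 and a regular gene symbol, and up to 4 members of each list with the smallest p, with the values of such genes in other comparisons. Irak1 is such a gene, and the other neighbours of Mecp2, H2-Aa, Cd74, Cd99l2 and Serpina3n were looked at after their values were seen. Comparisons, gene lists, the length limit and most alternatives were chosen before the data were examined. Matching on transcript GC and length, GENCODE spans, leaving out single libraries, leaving out Irak1 or Mecp2, and the count of splits for each list were added after. Group means carry standard deviations and log2 fold changes carry standard errors, and n is mice.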

Results

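RNA was sequenced from the forebrain (cortex and hippocampus) of male mice that lack MeCP2, a protein that binds methylated DNA and represses transcription, and of their wild-type littermates, 10 mice per genotype. A second cohort held 10 mice with the Rett syndrome mutation MeCP2 R306C, which breaks contact with the NCoR corepressor complex, and 10 wild-type littermates. Each forebrain lysate gave whole-cell, nuclear and chromatin-associated RNA, so the 40 mice gave 120 libraries. Another cohort measured visual cortex RNA from 6 mice without the DNA methyltransferase Dnmt3a in the nervous system (Nestin-cre) and 6 floxed controls, 4 females and 2 males per genotype. Mice lacking MeCP2 and their littermates were 8 weeks old, and those of the R306C and Dnmt3a cohorts 8 to 12 weeks. Reads counted in genes per library, in units of 1e6, came to 16.3 to 20.8, 17.4 to 24.5 and 18.7 to 25.5 for whole-cell, nuclear and chromatin-associated RNA of the MeCP2 knockout (KO) cohort, 14.3 to 21.9, 13.4 to 20.8 and 13.8 to 22.6 for the R306C cohort, and 17.9 to 34.7 for the Dnmt3a cohort. Whole-cell and visual cortex counts cover exons, and nuclear and chromatin-associated counts cover the whole gene body.

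Mecp2 mRNA was nearly absent from KO whole-cell RNA, with 33 to 99 exon counts per library against 3139 to 4072 in wild type. Its log2 fold change was -5.57 ± 0.10 (± standard error, adjusted p = 4.96e-26, lower in 10 of 10 KO libraries than the wild-type mean). Gene-body counts of Mecp2 moved the other way in the same mice and rose by 0.39 ± 0.08 in nuclear RNA (adjusted p = 0.00335) and by 0.81 ± 0.04 in chromatin-associated RNA (adjusted p = 2.01e-12). In the latter, log2 CPM (counts per 1e6 of a library) were 7.95 ± 0.11 in KO and 7.15 ± 0.06 in wild type (± standard deviation, n = 10 and 10). Irak1, a kinase of interleukin-1 signalling whose gene lies 2670 bp downstream of Mecp2 on the same strand, rose by 0.70 ± 0.03, 1.13 ± 0.05 and 1.35 ± 0.05 in whole-cell, nuclear and chromatin-associated RNA (adjusted p = 5.1e-16, 2.75e-13 and 2.88e-16, higher in 10 of 10 KO libraries each time). In R306C mice Mecp2 had log2 fold changes of 0.09, 0.05 and 0.04 in the 3 fractions (adjusted p = 0.462, 0.582 and 0.659), and it passed in whole-cell RNA with replicate number as a block (0.09, adjusted p = 0.00609) or with 2 surrogate variables (adjusted p = 0.00992). Irak1 did not pass in R306C (0.02, -0.09 and -0.05, adjusted p = 0.801, 0.323 and 0.646). Dnmt3a fell by 0.75 ± 0.12 in the Dnmt3a cKO visual cortex (adjusted p = 0.00125, log2 CPM 6.55 ± 0.28 against 7.32 ± 0.18, n = 6 and 6, lower in 6 of 6 cKO libraries), where Mecp2 had a log2 fold change of 0.08 (adjusted p = 0.646). Exon and gene-body counts of 1 gene were never compared directly, since they count different parts of it.

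**Figure D1:**
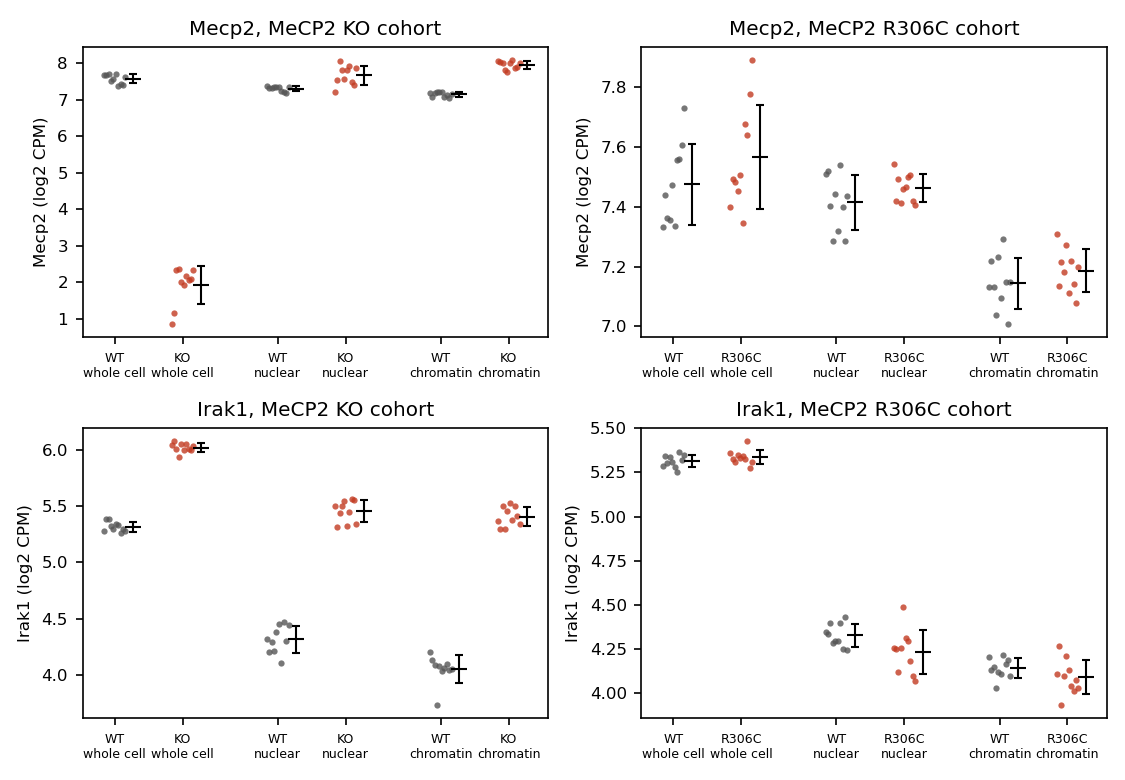
Log2 CPM of Mecp2 and Irak1 in every library of the MeCP2 KO and R306C cohorts, by fraction and genotype.

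**Figure D2:**
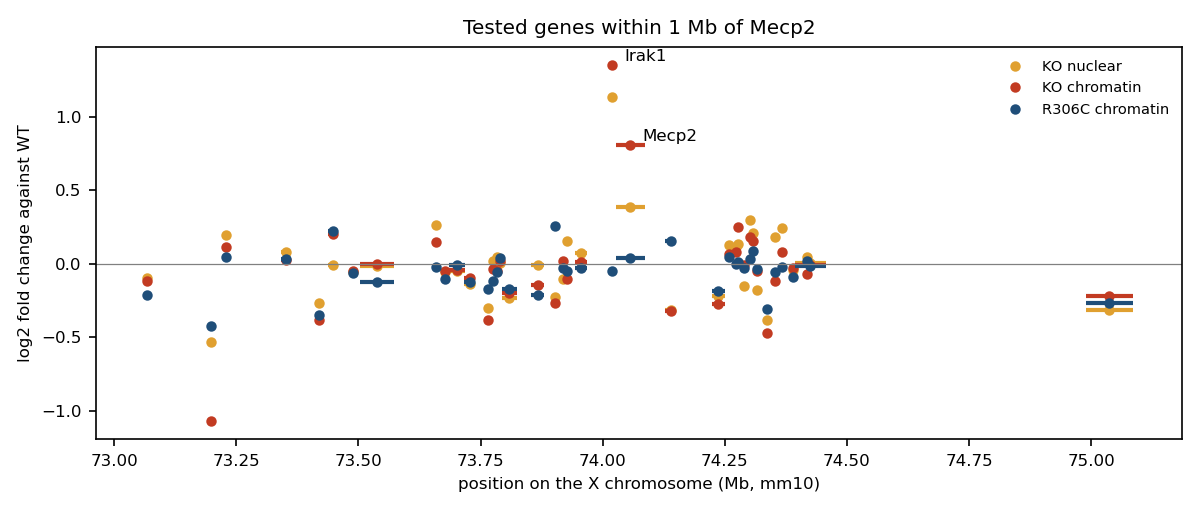
Log2 fold changes of the tested genes within 1 Mb of Mecp2, by position on the X chromosome. Shown are KO nuclear, KO chromatin-associated and R306C chromatin-associated RNA.

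Which steady-state transcripts depend on MeCP2 was asked in KO whole-cell RNA. Sdk1, a homophilic adhesion protein of synapses, rose by 0.71 ± 0.04 (36.1 ± 1.84 CPM in KO against 22.1 ± 1.43 in wild type, adjusted p = 8.67e-13, higher in 10 of 10 KO libraries). The teneurins Tenm3 and Tenm2, also large adhesion genes, rose by 0.49 and 0.32. Etnppl, an astrocyte lyase of phosphoethanolamine, rose by 1.07 ± 0.17 (adjusted p = 4.43e-05), Gli1, a transcription factor of hedgehog signalling, by 0.90, the imprinted Notch-ligand relative Dlk1 by 0.89, and the nuclear receptor gene Rora by 0.68. Pappa2, a protease of insulin-like growth factor binding proteins, fell by 1.67 ± 0.11 (1.73 ± 0.343 CPM in KO against 5.55 ± 0.771 in wild type, adjusted p = 5.25e-12, lower in 10 of 10 KO libraries). Among other genes that fell are the calcium sensor Tnnc1 (-1.22), the orexin receptor Hcrtr1 (-1.20), the secreted glycoprotein Stc1 (-1.17) and the T-type calcium channel Cacna1g (-0.74). In total 1341 genes were higher and 1426 lower of 14469 tested in edgeR, with a median absolute log2 fold change of 0.21 among them and 256 beyond 0.5. DESeq2 called 2929.

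Among 41 long synaptic adhesion genes, 19 rose and 4 fell in KO whole-cell RNA (23 up and 4 down adjusted over the list alone), and 18 did not pass. Camera gave the list adjusted p = 4.62e-06, and adjusted p = 0.207 with an estimated correlation. Nrxn2, a presynaptic neurexin, was among those that fell (-0.29). For scale, 21.5 percent of all genes longer than 100 kb rose and 8.18 percent fell. Of 20 cadherins and non-clustered protocadherins, 9 rose and 2 fell (10 up and 2 down adjusted over the list alone, adjusted p = 0.000462, adjusted p = 0.332 with an estimated correlation). Among them are the cell adhesion genes Cdh4 (0.44), Pcdh9 (0.45) and Cdh6 (0.42). The 14 neuronal splicing regulators of large genes had 7 that rose and 0 that fell (8 up and 0 down adjusted over the list alone, adjusted p = 0.000538, adjusted p = 0.207 with an estimated correlation). Members are the splicing factor Nova1 (0.40) and Auts2 (0.46), a regulator of chromatin and transcription that is not known as a splicing factor and stands in the list as it was fixed. Nuclear-retained long non-coding RNAs rose in 6 of 16 cases and fell in 0 (9 up and 0 down adjusted over the list alone, adjusted p = 0.00028, adjusted p = 0.207 with an estimated correlation). They include Meg3 at 0.46 and Snhg11 at 0.45. Imprinted genes rose in 8 and fell in 3 of 30 (11 up and 3 down adjusted over the list alone, adjusted p = 0.00282, adjusted p = 0.332 with an estimated correlation). Among them are the zinc-finger gene Plagl1 (0.46) and the retrotransposon-derived Peg10 (0.44) beside Dlk1. Neuropeptides fell in 6 of 19 and rose in 1 (1 up and 6 down adjusted over the list alone, adjusted p = 0.0275, adjusted p = 0.207 with an estimated correlation). The stress hormone gene Crh fell by 0.89, Adcyap1 (PACAP) by 0.45 and somatostatin (Sst) by 0.31. Genes reported earlier to change with MeCP2 loss rose in 4 and fell in 1 of 12 (8 up and 1 down adjusted over the list alone, adjusted p = 0.000957, adjusted p = 0.0313 with an estimated correlation). The transcriptional inhibitors Id3 (0.25) and Id2 (0.13) are members. Irak1 is a member of this list, and without it the values were adjusted p = 0.0266 and adjusted p = 0.207 with an estimated correlation.

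Markers of other cells and regions were read in the same KO whole-cell RNA. Oligodendrocyte precursor markers fell in 5 of 10 and rose in 0 (1 up and 6 down adjusted over the list alone, adjusted p = 0.0037, adjusted p = 0.168 with an estimated correlation). They include the receptors Gpr17 (-0.40) and Pdgfra (-0.28). Astrocyte markers fell in 4 of 12 and rose in 1 (2 up and 7 down adjusted over the list alone, adjusted p = 0.0426, adjusted p = 0.207 with an estimated correlation). Among them are the calcium-binding S100b (-0.27) and the water channel Aqp4 (-0.25). Microglia markers fell in 3 of 12 and rose in 1 (1 up and 4 down adjusted over the list alone, adjusted p = 0.0463, adjusted p = 0.369 with an estimated correlation). Here the protease Ctss fell (-0.21) and the purine receptor P2ry12 rose (0.25). Striatum markers rose in 6 of 12 and fell in 0 (7 up and 0 down adjusted over the list alone, adjusted p = 0.00424, adjusted p = 0.207 with an estimated correlation). Members are the regulator of G-protein signalling Rgs9 (0.21) and the receptor Adora2a (0.17). Small rises passed in 6 of 57 cytosolic ribosomal protein genes (6 up and 0 down adjusted over the list alone, adjusted p = 0.000324, adjusted p = 0.787 with an estimated correlation). The same held for 8 of 66 respiratory chain genes encoded in the nucleus (6 up and 0 down adjusted over the list alone, adjusted p = 0.0129, adjusted p = 0.787 with an estimated correlation). Both shares lie near that of all genes tested, where 1341 of 14469 were higher. Of 35 lists tested, 13 passed with the preset correlation, and genes reported earlier alone passed with the estimated one. The preset test also passed a median of 8 lists in random splits of these libraries, so members called over all genes are given first.

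Nuclear RNA, counted over gene bodies, was used to ask whether the changes of KO mice are already present in the nucleus. Dlk1 rose by 1.36 ± 0.21 (adjusted p = 0.000239, higher in 10 of 10 KO libraries), Etnppl by 0.82, Sdk1 by 0.73 and Bmper, a secreted regulator of bone morphogenetic proteins, by 0.73. Pappa2 fell by 1.18 ± 0.12 (adjusted p = 9.91e-07), the lipid transporter gene Abca8a by 1.08, the gastrin-releasing peptide gene Grp by 0.96 and Cacna1g by 0.74. The choroid plexus potassium channel Kcnj13 fell by 1.03. Dnmt3a fell by 0.21 ± 0.04 (adjusted p = 0.00235). In total 740 genes were higher and 1008 lower of 15224 (median absolute log2 fold change 0.27, 256 beyond 0.5, 2122 called in DESeq2). With 2 surrogate variables the balance turned, at 2489 higher and 2215 lower. Imprinted genes rose in 8 of 31 and fell in 0 (10 up and 0 down adjusted over the list alone, adjusted p = 0.000261, adjusted p = 0.731 with an estimated correlation). Cadherins and protocadherins rose in 5 of 20 (8 up and 0 down adjusted over the list alone, adjusted p = 0.000238, adjusted p = 0.771 with an estimated correlation). They include Cdh6 at 0.44 and Pcdh17 at 0.42. Long synaptic adhesion genes rose in 4 and fell in 1 of 41 (4 up and 1 down adjusted over the list alone, adjusted p = 0.00148, adjusted p = 0.795 with an estimated correlation). For scale, 7.18 percent of all genes longer than 100 kb rose here and 3.63 percent fell. Markers of the striatum rose in 6 of 12 and fell in 0 (9 up and 0 down adjusted over the list alone, adjusted p = 0.000305, adjusted p = 0.377 with an estimated correlation). Among them is the dopamine receptor Drd1 at 0.36. Excitatory neuron markers rose in 4 and fell in 1 of 14 (5 up and 1 down adjusted over the list alone, adjusted p = 0.0472, adjusted p = 0.771 with an estimated correlation). An example is the cortical transcription factor Tbr1 at 0.44. The other lists that passed were genes reported earlier (3 up and 1 down of 12, 6 up and 1 down adjusted over the list alone, adjusted p = 0.00276, adjusted p = 0.377 with an estimated correlation) and glucocorticoid-induced genes (1 up and 0 down of 15, 4 up and 0 down adjusted over the list alone, adjusted p = 0.000305, adjusted p = 0.771 with an estimated correlation). Also among them were respiratory chain genes (4 up and 0 down of 66, 0 up and 0 down adjusted over the list alone, adjusted p = 0.000214, adjusted p = 0.777 with an estimated correlation) and ribosomal protein genes (2 up and 0 down of 57, 0 up and 0 down adjusted over the list alone, adjusted p = 3.01e-06, adjusted p = 0.777 with an estimated correlation). Without Irak1 the genes reported earlier did not pass in nuclear RNA (adjusted p = 0.0792, adjusted p = 0.771 with an estimated correlation).

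Chromatin-associated RNA, enriched for transcripts still held at the template, addressed the same question closer to transcription. Bmper rose by 0.81 ± 0.06 (adjusted p = 7.64e-10, higher in 10 of 10 KO libraries), Sdk1 by 0.83, Dlk1 by 1.11 and Trabd2b, a protease that acts on Wnt proteins, by 0.70. Abca8a fell by 1.10 ± 0.09 (adjusted p = 9.06e-09, lower in 10 of 10 KO libraries), Pappa2 by 1.09, Grp by 1.08, the growth factor gene Fgf10 by 0.85 and Cacna1g by 0.71. Dnmt3a had a log2 fold change of -0.15 here (adjusted p = 0.0609) and -0.07 in whole-cell RNA (adjusted p = 0.352). The value here passed with a limit of mean log2 CPM at 1 (adjusted p = 0.048) and with 2 surrogate variables (adjusted p = 0.0142). In total 717 genes were higher and 862 lower of 15140 (median absolute log2 fold change 0.27, 235 beyond 0.5, 1821 called in DESeq2). The counts with 2 surrogate variables were 1375 higher and 1401 lower. Without wild-type chromatin replicate 1, a library left out after results were seen, the balance turned, at 860 higher and 823 lower. Imprinted genes rose in 6 of 31 (10 up and 0 down adjusted over the list alone, adjusted p = 0.00142, adjusted p = 0.741 with an estimated correlation). They include Plagl1 (0.30) and the zinc-finger gene Peg3 (0.24). Long synaptic adhesion genes rose in 5 and fell in 1 of 41 (8 up and 1 down adjusted over the list alone, adjusted p = 0.00151, adjusted p = 0.954 with an estimated correlation). For scale, 12.2 percent of all genes longer than 100 kb rose here and 5.03 percent fell. Neuronal splicing regulators rose in 2 of 14 (3 up and 1 down adjusted over the list alone, adjusted p = 0.0466, adjusted p = 0.878 with an estimated correlation). An example is the RNA-binding Elavl4 at 0.29. Oligodendrocyte precursor markers fell in 4 of 10 (0 up and 6 down adjusted over the list alone, adjusted p = 0.00148, adjusted p = 0.562 with an estimated correlation). Members are the complement-like C1ql1 (-0.66) and Gpr17 (-0.36). Striatum markers rose in 3 of 12 (6 up and 0 down adjusted over the list alone, adjusted p = 0.00151, adjusted p = 0.562 with an estimated correlation). The other lists that passed in chromatin-associated RNA were genes reported earlier (2 up and 2 down of 12, 3 up and 2 down adjusted over the list alone, adjusted p = 0.0156, adjusted p = 0.36 with an estimated correlation) and cadherins and protocadherins (2 up and 1 down of 20, 3 up and 1 down adjusted over the list alone, adjusted p = 0.0176, adjusted p = 0.923 with an estimated correlation). Also among them were glucocorticoid-induced genes (1 up and 0 down of 15, 1 up and 0 down adjusted over the list alone, adjusted p = 0.00216, adjusted p = 0.79 with an estimated correlation) and microglia markers (0 up and 1 down of 12, 0 up and 1 down adjusted over the list alone, adjusted p = 0.0105, adjusted p = 0.79 with an estimated correlation). Respiratory chain genes passed with 0 of 66 called (0 up and 0 down adjusted over the list alone, adjusted p = 0.0102, adjusted p = 0.881 with an estimated correlation). Without Irak1 the genes reported earlier had 1 up and 2 down of 11 and did not pass (adjusted p = 0.3, adjusted p = 0.79 with an estimated correlation). Of 34 lists, 9 passed in nuclear and 10 in chromatin-associated RNA, and 0 in either with an estimated correlation. Random splits of the same libraries passed a median of 12 and 11, more than genotype did. Across the 3 KO fractions 298 genes were higher and 244 lower each time.

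Whether a mutant that is still made but cannot bind the corepressor alters the same transcripts was asked in R306C whole-cell RNA. Dlk1 rose by 0.81 ± 0.12 (adjusted p = 9.15e-05, higher in 10 of 10 R306C libraries), the lipid droplet coat gene Plin4 by 0.74, the transcription factor Runx2 by 0.65 and Ptgs2, the inducible cyclooxygenase, by 0.73. Grp fell by 0.96 ± 0.07 (3.56 ± 0.292 CPM in R306C against 6.94 ± 0.709 in wild type, adjusted p = 5.05e-09, lower in 10 of 10 R306C libraries), Tnnc1 by 1.22, Pappa2 by 0.96, the hexokinase-like Hkdc1 by 0.79 and Cacna1g by 0.66. Dnmt3a had a log2 fold change of -0.10 (adjusted p = 0.493, 0.0265 with 2 surrogate variables). In total 450 genes were higher and 599 lower of 14467 (median absolute log2 fold change 0.26, 137 beyond 0.5, 1279 called in DESeq2). The balance turned with replicate number as a block, at 1483 higher and 1331 lower, in a table where mice of the same number resemble each other across genotype. It also turned with 2 surrogate variables, at 1669 higher and 1490 lower.

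Glutamate receptor genes fell in 5 of 23 and rose in 0 in R306C whole-cell RNA (0 up and 7 down adjusted over the list alone, adjusted p = 0.00854, adjusted p = 0.368 with an estimated correlation). They include the NMDA receptor subunits Grin2d (-0.55) and Grin3a (-0.35) and the metabotropic receptor Grm3 (-0.27). Imprinted genes rose in 8 and fell in 1 of 30 (8 up and 1 down adjusted over the list alone, adjusted p = 0.0095, adjusted p = 0.192 with an estimated correlation). Among them are Peg10 (0.46) and Plagl1 (0.36). Clustered beta protocadherins fell in 1 of 21 (0 up and 8 down adjusted over the list alone, adjusted p = 6.24e-05, adjusted p = 0.368 with an estimated correlation). The member is Pcdhb9 (-0.22). Choroid plexus and ependyma markers fell in 4 of 12 and rose in 0 (0 up and 6 down adjusted over the list alone, adjusted p = 6.49e-05, adjusted p = 0.192 with an estimated correlation). Members are the folate receptor Folr1 (-0.67), Kl, the klotho gene (-0.47), and the water channel Aqp1 (-0.58). Oligodendrocyte precursor markers fell in 4 of 10 (0 up and 5 down adjusted over the list alone, adjusted p = 0.0095, adjusted p = 0.192 with an estimated correlation). They include Gpr17 (-0.36) and the proteoglycan Cspg4 (-0.23). Long synaptic adhesion genes did not pass as a list (adjusted p = 0.218, adjusted p = 0.86 with an estimated correlation), although 4 rose and 2 fell of 41 (6 up and 4 down adjusted over the list alone), with Sdk1 at 0.54 and Tenm3 at 0.37. Neuropeptides did not pass either (adjusted p = 0.171, adjusted p = 0.517 with an estimated correlation). Among them are 7 that fell and 2 that rose of 19 (3 up and 8 down adjusted over the list alone). Cytosolic ribosomal protein genes passed as a list with 1 of 57 higher (0 up and 0 down adjusted over the list alone, adjusted p = 2.46e-08, adjusted p = 0.54 with an estimated correlation). The other lists that passed were respiratory chain genes (4 up and 0 down of 66, 0 up and 0 down adjusted over the list alone, adjusted p = 6.23e-07, adjusted p = 0.628 with an estimated correlation) and cholesterol synthesis genes (0 up and 2 down of 23, 0 up and 2 down adjusted over the list alone, adjusted p = 0.0249, adjusted p = 0.504 with an estimated correlation). Also among them were genes reported earlier (1 up and 1 down of 12, 4 up and 1 down adjusted over the list alone, adjusted p = 0.0332, adjusted p = 0.192 with an estimated correlation) and striatum markers (0 up and 0 down of 12, 1 up and 0 down adjusted over the list alone, adjusted p = 0.049, adjusted p = 0.368 with an estimated correlation). Random splits passed a median of 8 lists against 10. With the block 16 lists passed against 10, and the calls of the lists above did not change. The lists gained were GABA receptors (adjusted p = 0.0183 with the block, 0.0512 without), neuronal splicing regulators (0.019 and 0.103), activity-regulated early response genes (0.0453 and 0.0862), glucocorticoid-induced genes (0.0378 and 0.0512), mitochondrially encoded genes (0.0328 and 0.182) and replication-dependent histone genes (0.0355 and 0.0512).

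R306C nuclear and chromatin-associated RNA were read for the same question inside the nucleus. Dlk1 rose by 0.76 ± 0.14 and 0.85 ± 0.20 in the 2 fractions (adjusted p = 0.00126 and 0.0123), and Inhba, a subunit of activin, by 0.70 and 0.76. Pappa2 fell by 0.98 ± 0.12 and 0.90 ± 0.11 (adjusted p = 2.42e-05 and 2.84e-05, lower in 10 of 10 and 10 of 10 R306C libraries), Grp by 0.77 and 0.90, the sodium channel Scn9a by 0.86 and 0.74 and Cacna1g by 0.54 and 0.60. Dnmt3a had log2 fold changes of -0.02 (adjusted p = 0.866) and -0.07 (adjusted p = 0.436, 0.0469 with 2 surrogate variables). In nuclear RNA 386 genes were higher and 459 lower of 14950 (1001 in DESeq2), and in chromatin-associated RNA 284 and 423 of 14932 (838 in DESeq2). The counts with 2 surrogate variables were 769 higher and 932 lower in nuclear and 721 higher and 842 lower in chromatin-associated RNA. Glutamate receptor genes fell in 4 of 23 in nuclear RNA (0 up and 4 down adjusted over the list alone, adjusted p = 0.0235, adjusted p = 0.959 with an estimated correlation). In chromatin-associated RNA 3 of 23 fell (0 up and 4 down adjusted over the list alone, adjusted p = 0.0286, adjusted p = 0.98 with an estimated correlation). Grin3a fell by 0.37 and 0.30 in the 2 fractions and Grin2d by 0.43 and 0.51. Imprinted genes rose in 4 of 30 in chromatin-associated RNA (6 up and 1 down adjusted over the list alone, adjusted p = 0.0381, adjusted p = 0.354 with an estimated correlation). Choroid plexus and ependyma markers fell in 3 of 12 in nuclear RNA (0 up and 4 down adjusted over the list alone, adjusted p = 0.000979, adjusted p = 0.959 with an estimated correlation). Members are the thyroid hormone carrier Ttr at -0.80 and Kl at -0.57. Markers of this tissue fell in 2 of 11 in chromatin-associated RNA (0 up and 5 down adjusted over the list alone, adjusted p = 0.0257, adjusted p = 0.98 with an estimated correlation). Oligodendrocyte precursor markers fell in 3 of 10 in nuclear RNA (0 up and 4 down adjusted over the list alone, adjusted p = 0.00162, adjusted p = 0.959 with an estimated correlation). The chromatin-associated fraction had 2 of 10 (0 up and 3 down adjusted over the list alone, adjusted p = 0.0152, adjusted p = 0.354 with an estimated correlation). They include the proteoglycan Vcan at -0.46 and -0.42. The other lists that passed in nuclear RNA were mitochondrially encoded genes (0 up and 1 down of 7, 0 up and 4 down adjusted over the list alone, adjusted p = 0.00146, adjusted p = 0.959 with an estimated correlation) and activity-regulated late response genes (1 up and 0 down of 14, 2 up and 0 down adjusted over the list alone, adjusted p = 0.0324, adjusted p = 0.959 with an estimated correlation). Also among them were microglia markers (0 up and 0 down of 12, 0 up and 1 down adjusted over the list alone, adjusted p = 0.0318, adjusted p = 0.959 with an estimated correlation) and respiratory chain genes (0 up and 0 down of 66, 0 up and 0 down adjusted over the list alone, adjusted p = 0.0375, adjusted p = 0.97 with an estimated correlation). In chromatin-associated RNA they were cadherins and protocadherins (3 up and 1 down of 20, 7 up and 1 down adjusted over the list alone, adjusted p = 0.042, adjusted p = 0.98 with an estimated correlation) and late response genes (1 up and 0 down of 13, 1 up and 0 down adjusted over the list alone, adjusted p = 0.0359, adjusted p = 0.98 with an estimated correlation). Of 34 lists, 7 and 6 passed, and 0 with an estimated correlation. Random splits of the same libraries passed a median of 10 and 9, more than genotype did. Across the 3 R306C fractions 117 genes were higher and 165 lower each time.

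Whether loss of MeCP2 and the R306C mutation differ in their effects was asked gene by gene within each fraction. Cacna1g fell in all 6 comparisons, by 0.74 in KO and 0.66 in R306C whole-cell RNA, and Dlk1, Pappa2 and Grp also moved the same way in all 6, with Grp at -1.08 in KO and -0.90 in R306C chromatin-associated RNA. Genes called with both alleles went the same way in 808 of 809 cases in whole-cell RNA. Of these, 341 were higher with both where 41.9 are expected without association, and 467 lower with both where 59 are. Directions matched in 396 of 396 in nuclear RNA and in 427 of 428 in chromatin-associated RNA. For the median gene called in KO, the R306C effect was 0.649, 0.393 and 0.585 of the KO effect in whole-cell, nuclear and chromatin-associated RNA. These genes were chosen for passing in KO, which tends to overstate their KO effect and lowers the share. The shares therefore do not show that R306C acts more weakly. Across all genes the 2 effects correlated at 0.584, 0.487 and 0.559 (Pearson), where 100 joint permutations of genotype reached at most 0.504, 0.469 and 0.337. The Spearman correlations were 0.577, 0.383 and 0.517, and the permutations reached at most 0.599, 0.571 and 0.355. By rank the highest permutation was therefore above the real value in whole-cell and nuclear RNA and below it in chromatin-associated RNA.

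**Figure D3:**
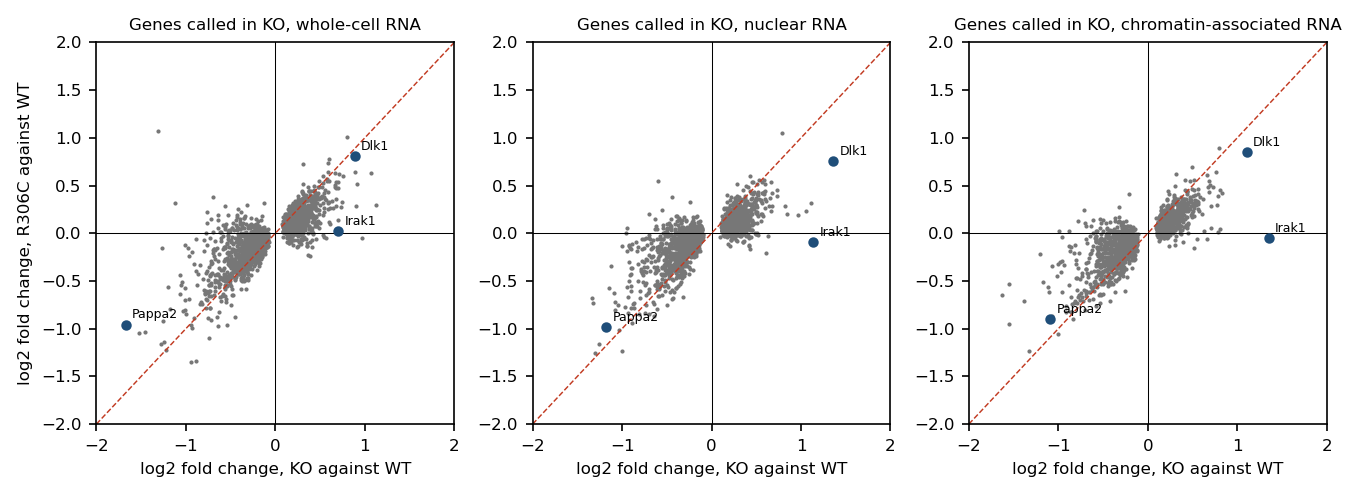
Log2 fold changes in MeCP2 R306C against those in MeCP2 KO for genes called in KO, in whole-cell, nuclear and chromatin-associated RNA. 1 gene of whole-cell RNA lies outside the axes.

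A test of the difference between the alleles (R306C effect minus KO effect) called 7 of 14783 genes in whole-cell RNA (10 in DESeq2, 854 with unadjusted p under 0.05), 1 of 15352 in nuclear RNA (51 and 1867) and 2 of 15310 in chromatin-associated RNA (11 and 958). The unadjusted shares were 5.78, 12.2 and 6.26 percent. Simulated 1.2-fold differences were recovered in 34, 20 and 34 percent of cases, and 1.5-fold ones in 94, 84 and 90 percent. Few calls therefore do not show that the alleles act alike. With replicate number as a block the count in whole-cell RNA was 45 (23 higher and 22 lower, against 6 higher and 1 lower without). Mecp2 itself differed in whole-cell RNA by 5.66 (adjusted p = 2.12e-34) and in chromatin-associated RNA by -0.77 (adjusted p = 2.07e-13). Irak1 differed by -0.68, -1.22 and -1.40 in whole-cell, nuclear and chromatin-associated RNA (adjusted p = 1.55e-18, 2.63e-17 and 1.4e-21). Pappa2 fell further in KO than in R306C whole-cell RNA (difference 0.72, adjusted p = 0.0372). The class II antigen presentation genes H2-Aa and Cd74 differed by 1.45 and 0.99 (adjusted p = 0.00251 and 0.0395), and H2-Aa fell by 1.12 in KO (adjusted p = 5.64e-06) with 0.32 in R306C (adjusted p = 0.334). The last pair was picked after its values were seen, and each allele was measured in its own cohort, so a difference of alleles here includes any difference of cohorts. KO-cohort mice were 8 weeks old and R306C-cohort mice 8 to 12 weeks.

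A further question was whether an effect on RNA differs between chromatin-associated and nuclear RNA. Sdk1 rose by 0.73 in nuclear and 0.83 in chromatin-associated RNA of KO mice, Bmper by 0.73 and 0.81, and Cacna1g fell by 0.74 and 0.71. The difference between fractions was called for 0 of 15485 genes in KO (lowest adjusted p = 0.89, 0 in DESeq2, 175 with unadjusted p under 0.05) and 0 of 15233 in R306C (lowest adjusted p = 1, 0 in DESeq2, 160 with unadjusted p under 0.05). Both fractions come from 1 lysate, which this fit does not model. Its unadjusted p fell under 0.05 in 1.13 and 1.05 percent of genes, fewer than the 5 percent expected without any difference, so it is conservative. With the mouse as a block 0 genes were called in KO (lowest adjusted p = 0.304, 348 with unadjusted p under 0.05) and 0 in R306C (lowest adjusted p = 1, 626 with unadjusted p under 0.05). KO effects correlated at 0.585 between whole-cell and nuclear, 0.636 between whole-cell and chromatin-associated and 0.811 between nuclear and chromatin-associated RNA, and R306C effects at 0.653, 0.631 and 0.748. Permutation of genotype over the same mice gave at most 0.41, 0.318 and 0.564 for KO and 0.403, 0.389 and 0.658 for R306C. Spearman correlations were 0.493, 0.581 and 0.774 for KO (permutations at most 0.394, 0.303 and 0.565) and 0.536, 0.513 and 0.684 for R306C (0.42, 0.388 and 0.691). The highest permutation lay above the real value between nuclear and chromatin-associated RNA of R306C. Both fractions come from the same mice, which raises these correlations. In subsets of the KO mice, nuclear and chromatin-associated effects correlated at 0.718 within the same mice and 0.585 between disjoint mice. For R306C the values were 0.613 and 0.490. In simulated counts in which libraries of 1 mouse stay tied, the blocked test recovered 34 percent of 1.2-fold and 98 percent of 1.5-fold differences in KO, and 66 and 98 percent in R306C. On the real counts its unadjusted p fell under 0.05 in 2.25 percent of genes in KO and 4.11 percent in R306C. These shares also lie below 5 percent, so recovery on real counts may be lower than in the simulation.

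The series asks about long genes, and genes were split at a gene span of 100 kb. In KO whole-cell RNA 482 of 2237 genes longer than 100 kb were higher and 183 lower, among them Sdk1, Rora, Tenm3 and Auts2, while 856 of 12198 shorter genes were higher and 1235 lower. Long genes called in KO nuclear RNA were higher in 168 and lower in 85 cases (shorter genes 571 and 921), and in KO chromatin-associated RNA in 286 and 118 (shorter genes 430 and 741). R306C gave 178 and 93, 129 and 96, and 109 and 75 long genes in whole-cell, nuclear and chromatin-associated RNA, with 272 and 504, 257 and 363, and 175 and 347 shorter genes. With replicate number as a block R306C whole-cell RNA had 421 and 242 long and 1061 and 1086 shorter genes higher and lower. With 2 surrogate variables the long genes of R306C nuclear RNA turned, at 243 higher and 250 lower, and were 464 and 261 in whole-cell and 293 and 183 in chromatin-associated RNA of R306C and 636 and 252 and 611 and 176 in KO nuclear and chromatin-associated RNA. Above 400 kb the median log2 fold change was 0.10, 0.12 and 0.09 in the KO fractions and 0.04, -0.02 and -0.00134 in those of R306C, and 138 such genes were higher and 17 lower in KO whole-cell RNA. In the Dnmt3a cKO the long genes split into 85 higher and 79 lower, with a median of -0.02 above 400 kb, and with 2 surrogate variables into 157 and 158.

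**Figure D4:**
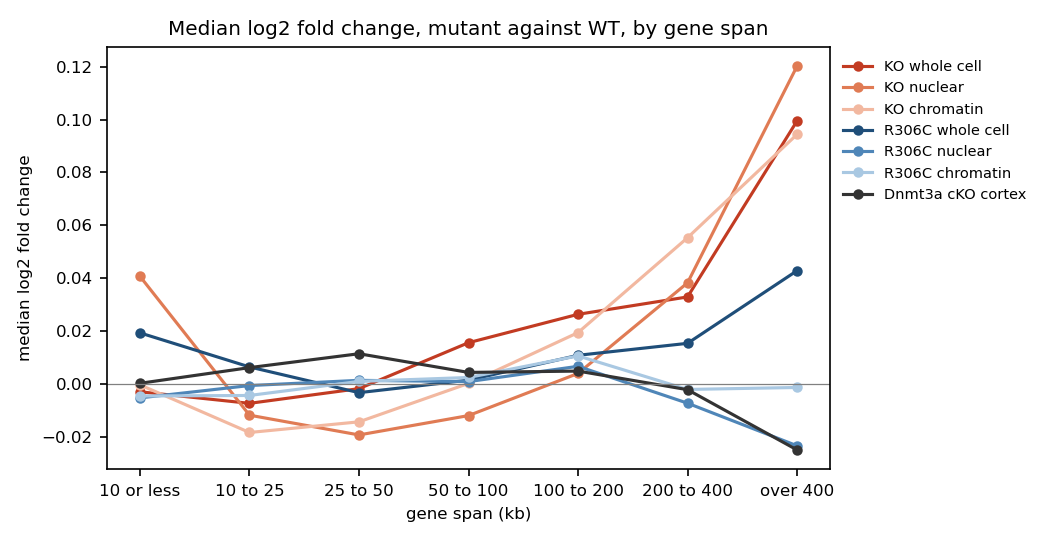
Median log2 fold change of genes by gene span for each comparison.

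A long-gene index was taken for each library as the mean log2 CPM of genes over 100 kb minus that of other genes. In KO whole-cell RNA it was 0.928 ± 0.0408 against 0.873 ± 0.042 in wild type, a difference of 0.0556 ± 0.0185 (standard error), with 10 of 10 KO libraries above the wild-type mean. The permutation test gave p = 0.0087 and p = 0.061 adjusted over the 7 comparisons, so the difference did not pass in the main setting. With replicate number as a block it passed (adjusted p = 0.041). In the other settings, 3 of them added after results were seen, adjusted p ran from 0.00049 to 0.44. The other differences did not pass either: 0.0412 in KO nuclear (adjusted p = 0.8), 0.059 in KO chromatin-associated (adjusted p = 0.52), 0.0277, 0.00762 and 0.0184 in R306C whole-cell, nuclear and chromatin-associated RNA (adjusted p = 0.8, 0.88 and 0.86, and 0.13 for whole-cell RNA with the block) and -0.0133 in the Dnmt3a cKO (adjusted p = 0.8). Nor did the index shift of mutants differ between chromatin-associated and nuclear RNA in KO (0.0189, permutation p = 0.81) or R306C (0.0126, permutation p = 0.77). The index also varies between mice of 1 genotype, where it follows the first principal component of KO whole-cell libraries with a Pearson correlation of 0.955 (Spearman 0.896, permutation p = 1e-05, adjusted p = 1.4e-05 over 7).

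**Figure D5:**
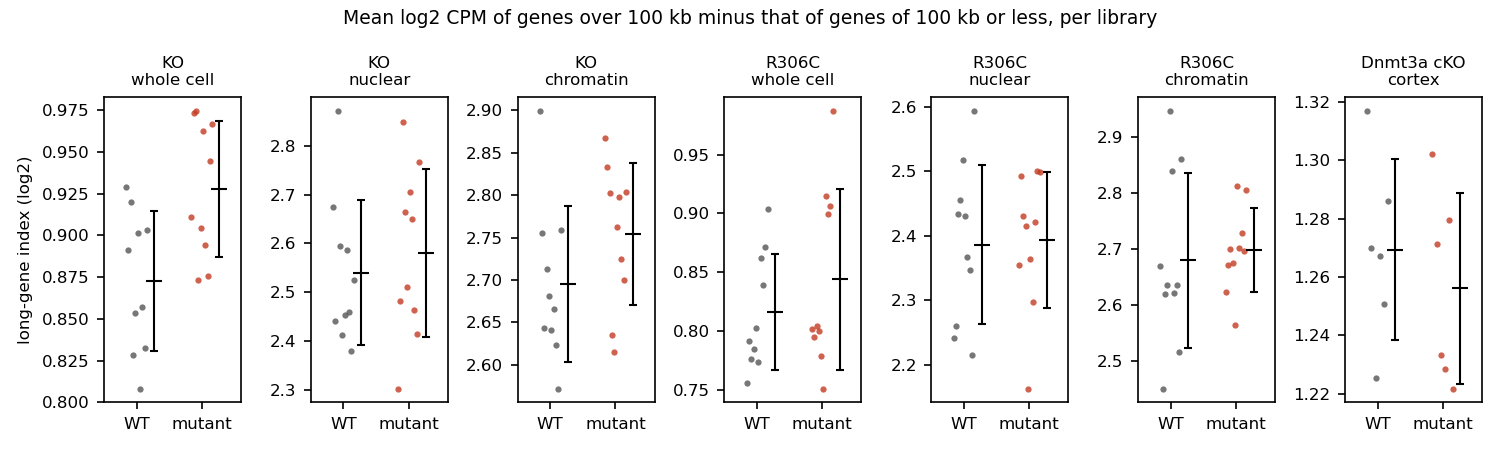
Long-gene index of every library by cohort, fraction and genotype.

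Which transcripts depend on DNA methylation set by Dnmt3a was asked in visual cortex RNA. Mab21l1, a developmental gene of nucleotidyltransferase fold, rose by 4.54 ± 0.20 (15.7 ± 2.36 CPM in cKO against 0.683 ± 0.316 in control, adjusted p = 1.43e-09, higher in 6 of 6 cKO libraries). Dlk1 rose by 4.77 ± 0.61 with wide spread (8.94 ± 9.83 CPM in cKO against 0.334 ± 0.157 in control, adjusted p = 0.000236, higher in 6 of 6 cKO libraries), the transmembrane glycoprotein gene Gpnmb by 2.42 and the cell polarity gene Crb2 by 1.91. The lactate transporter Slc16a3 fell by 1.74 (adjusted p = 4.95e-06), Abi3bp, a matrix protein gene, by 1.82, and the Wnt antagonist Frzb, Tnnc1 and the transcription factor Dach1 had log2 fold changes of -1.65, -1.54 and -1.44. In total 271 genes were higher and 241 lower of 14771 (median absolute log2 fold change 0.52, 269 beyond 0.5, 805 called in DESeq2). With 2 surrogate variables the balance turned, at 509 higher and 527 lower. Potassium channels fell in 8 of 26 and rose in 0 (1 up and 11 down adjusted over the list alone, adjusted p = 1.96e-09, adjusted p = 0.0346 with an estimated correlation). Among them are the sodium-activated Kcnt2 (-0.55), the Kv4 partner Kcnip4 (-0.42) and the fast Kv3 channel Kcnc2 (-0.33). GABA receptors fell in 4 of 14 (0 up and 9 down adjusted over the list alone, adjusted p = 1.34e-06, adjusted p = 0.2 with an estimated correlation). Members are the subunits Gabra1 (-0.40), Gabrd (-0.35) and Gabrg1 (-0.52). Gabrg1 did not pass without cKO replicate 2 (log2 fold change -0.473, adjusted p = 0.0754), a library left out after results were seen. That library stands apart on the second principal component, at -24.78 where the next lowest library has -8.70. Gabrg1 did not pass with a limit of mean log2 CPM at 1 either (adjusted p = 0.0556). Neuropeptides fell in 8 and rose in 1 of 16 (1 up and 8 down adjusted over the list alone, adjusted p = 0.000677, adjusted p = 0.122 with an estimated correlation). They include proenkephalin (Penk, -0.94) and the tachykinin gene Tac2 (-0.83). Cadherins and protocadherins fell in 4 of 20 (1 up and 5 down adjusted over the list alone, adjusted p = 0.00849, adjusted p = 0.307 with an estimated correlation). An example is Pcdh10 at -0.22. Beside these falls of neuronal genes, endothelial and pericyte markers passed as a list with 1 of 12 lower (0 up and 1 down adjusted over the list alone, adjusted p = 0.0304, adjusted p = 0.232 with an estimated correlation). The member is vitronectin (Vtn, -0.48).

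Glutamate receptors fell in 2 of 23 in the Dnmt3a cKO (1 up and 2 down adjusted over the list alone, adjusted p = 0.0112, adjusted p = 0.243 with an estimated correlation). An example is the AMPA receptor subunit Gria4 at -0.28, which did not pass without cKO replicate 2 (log2 fold change -0.245, adjusted p = 0.0568). Imprinted genes rose in 3 of 30 (3 up and 0 down adjusted over the list alone, adjusted p = 0.00655, adjusted p = 0.152 with an estimated correlation). They include the growth factor Igf2 (0.51) and Peg3 (0.31) beside Dlk1. Neuronal splicing regulators rose in 2 of 14 (3 up and 0 down adjusted over the list alone, adjusted p = 0.0169, adjusted p = 0.231 with an estimated correlation). They are Nova1 at 0.39 and Auts2, not known as a splicing factor, at 0.65. Nuclear-retained long non-coding RNAs rose in 1 of 18 (2 up and 0 down adjusted over the list alone, adjusted p = 0.000103, adjusted p = 0.243 with an estimated correlation). The member is Malat1 (0.29). Striatum markers fell in 3 and rose in 1 of 10 (1 up and 4 down adjusted over the list alone, adjusted p = 0.0398, adjusted p = 0.214 with an estimated correlation). Members are the preprotachykinin gene Tac1 at -0.79 and the phosphatase inhibitor Ppp1r1b at 0.86. Long synaptic adhesion genes did not pass (adjusted p = 0.242, adjusted p = 0.74 with an estimated correlation): 4 rose, such as Tenm3 (0.30), and 4 fell, such as Nrxn1 (-0.25), of 41 (5 up and 7 down adjusted over the list alone). The call of Malat1 ended without a filter (adjusted p = 0.0724) and that of Peg3 under 3 alternatives (adjusted p of at most 0.0549). Lists that passed without a member called over all genes were clustered beta protocadherins (21 genes, 0 up and 0 down adjusted over the list alone, adjusted p = 0.0216, adjusted p = 0.579 with an estimated correlation) and cholesterol synthesis genes (23 genes, 0 up and 0 down adjusted over the list alone, adjusted p = 0.00612, adjusted p = 0.569 with an estimated correlation). Also among them were mitochondrially encoded genes (8 genes, 0 up and 1 down adjusted over the list alone, adjusted p = 0.00612, adjusted p = 0.522 with an estimated correlation) and blood markers (5 genes, 0 up and 1 down adjusted over the list alone, adjusted p = 0.0303, adjusted p = 0.569 with an estimated correlation). Of 35 lists, 14 passed, and potassium channels alone passed with an estimated correlation. Random splits of the same libraries passed a median of 8. In simulated counts the test found 22 percent of 1.2-fold and 86 percent of 1.5-fold changes here, against 78 and 100 percent in KO whole-cell RNA, so fewer calls do not stand for fewer changes.

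The reach of Dnmt3a and MeCP2 over shared genes was compared through genes called in both. Dlk1, Tenm3, Bmper and the stress peptide binding protein gene Crhbp were higher, and Grp, the glycine receptor subunit Glra3 and Hkdc1 lower, in the Dnmt3a cKO and in all 6 MeCP2 comparisons, with 22 genes higher and 14 lower in all 7 of 13677 tested in each. Grp fell by 0.62 in the Dnmt3a cKO (adjusted p = 0.00452), whereas Cacna1g had a log2 fold change of 0.02 there (adjusted p = 0.974) and Pappa2 of -0.82 (adjusted p = 0.142). Of 207 genes called in the Dnmt3a cKO and in KO whole-cell RNA, 175 went the same way (93 both higher against 24.2 expected, 82 both lower against 22.8). Across all genes the Dnmt3a effect correlated with that of KO at 0.272 in whole-cell RNA (highest of 100 joint permutations 0.213), 0.169 in nuclear (0.223) and 0.248 in chromatin-associated RNA (0.227), and with that of R306C at 0.242 (0.336), 0.238 (0.229) and 0.208 (0.254). The permutations reached the real value in 4 draws for KO nuclear RNA and in 2 and 2 for R306C whole-cell and chromatin-associated RNA. Spearman correlations were 0.276, 0.1 and 0.205 with KO and 0.208, 0.222 and 0.189 with R306C, and the highest permutation was above each of them (0.302, 0.251, 0.291, 0.394, 0.304 and 0.308). Sex and brain region of the Dnmt3a cohort differ from those of the forebrain cohorts, and its age range from that of the KO cohort.

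How chromatin-associated RNA differs from nuclear RNA was asked in the wild-type mice of both cohorts. Mitochondrially encoded transcripts were depleted, with log2 fold changes of the cytochrome b gene CYTB of -1.83 ± 0.14 in the KO cohort and -1.77 ± 0.14 in the R306C cohort (adjusted p = 3.57e-09 and 1.23e-09, lower in 10 of 10 and 10 of 10 chromatin libraries). The NADH dehydrogenase subunit ND4 had -1.83 and -1.72. The postsynaptic scaffold Dlg2 rose by 0.58 and the neuregulin Nrg3 by 0.59 in the KO cohort, and the ion channel Asic2 by 1.17 and the splicing factor Rbfox1 by 0.96 in the R306C cohort. Long synaptic adhesion genes rose in 28 and fell in 1 of 41 in the KO cohort (31 up and 1 down adjusted over the list alone, adjusted p = 1.22e-09, adjusted p = 0.335 with an estimated correlation). In the R306C cohort 39 rose and 0 fell (40 up and 0 down adjusted over the list alone, adjusted p = 3.37e-11, adjusted p = 0.496 with an estimated correlation). Nuclear-retained long non-coding RNAs rose in 7 of 17 in the KO cohort (7 up and 0 down adjusted over the list alone, adjusted p = 0.000924, adjusted p = 0.202 with an estimated correlation). The R306C cohort had 15 of 17 (15 up and 0 down adjusted over the list alone, adjusted p = 5.4e-06, adjusted p = 0.297 with an estimated correlation), with the imprinted Meg3 at 0.67. Cytosolic ribosomal protein genes fell in 53 of 57 in the KO cohort (0 up and 54 down adjusted over the list alone, adjusted p = 1.57e-21, adjusted p = 0.257 with an estimated correlation) and in 54 of 57 in the R306C cohort. The latter had 0 up and 55 down adjusted over the list alone (adjusted p = 2.01e-15, adjusted p = 0.496 with an estimated correlation). Neuropeptides fell in 16 of 18 in the KO cohort (1 up and 16 down adjusted over the list alone, adjusted p = 9.32e-07, adjusted p = 0.257 with an estimated correlation). Sst fell by 1.08 in the R306C cohort, where 16 of 17 neuropeptides fell (0 up and 16 down adjusted over the list alone, adjusted p = 6.88e-09, adjusted p = 0.297 with an estimated correlation). All 7 mitochondrially encoded genes tested fell in the KO cohort (0 up and 7 down adjusted over the list alone, adjusted p = 4.49e-11, adjusted p = 0.202 with an estimated correlation) and all 7 in the R306C cohort (0 up and 7 down adjusted over the list alone, adjusted p = 1.42e-07, adjusted p = 0.297 with an estimated correlation). Microglia markers fell in 8 of 12 in the KO cohort (0 up and 9 down adjusted over the list alone, adjusted p = 0.000374, adjusted p = 0.3 with an estimated correlation). Of 15223 genes tested in the KO cohort 2393 were higher and 3103 lower in chromatin-associated RNA, and of 14939 in the R306C cohort 3981 and 3795. With the mouse as a block the calls were 6538 and 9451, and 26 and 20 lists passed against 22 and 18 without it and a median of 11 and 11 in random splits. Mecp2 had log2 fold changes of -0.05 and -0.14 between the 2 fractions (adjusted p = 0.364 and 0.0122), and Dnmt3a of -0.04 and 0.40 (adjusted p = 0.608 and 1.26e-07).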

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

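Single libraries far from their group were looked for in 70 groups of values, where chance gives about 1 in 20, or 3.5, and 5 were found. As the share of the group's range that separates the library from the next, they were the total count of R306C-cohort wild-type chromatin replicate 2 (lowest, 0.484) and Dnmt3a in R306C-cohort wild-type nuclear replicate 10 (highest, 0.556). For Irak1 they were KO-cohort wild-type chromatin replicate 4 (lowest, 0.646), Dnmt3a-cohort control replicate 6 (highest, 0.79) and Dnmt3a cKO replicate 2 (highest, 0.737). Differences between the alleles (R306C minus KO, log2) passed for Mecp2 (5.66), Irak1 (-0.68), H2-Aa (1.45), Cd99l2 (0.38), Serpina3n (0.36), Pappa2 (0.72) and Cd74 (0.99) in whole-cell RNA. They also passed for Irak1 in nuclear RNA (-1.22), and for Irak1 (-1.40) and Mecp2 (-0.77) in chromatin-associated RNA.

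For the gain of Mecp2 gene-body and Irak1 counts in KO, the tests of neighbouring genes and of R306C were chosen after their results were seen, and the test across mice before. The 38 other tested genes within 1 Mb had a median log2 fold change of -0.0457 (bootstrap standard error 0.0219) in chromatin-associated RNA, where a change of the whole segment called for at least 0.27. A median does not exclude changes of single neighbours, of which 4 were called. All 4 were lower in KO: Zfp92 (-0.382), Pdzd4 (-0.195), Flna (-0.275) and Plxna3 (-0.472). Irak1 moved by -0.0488 in R306C, where loss of MeCP2 function as for other genes called for 0.792. A response to lost corepressor contact, of the median size seen for other genes, therefore does not account for it. R306C protein is still made, so a MeCP2 function that it keeps was not tested. The 0.792 also applies a median share over many genes to 1 gene in another cohort. That share is lowered by the choice of genes that passed in KO. Transcription running on from the Mecp2 allele into Irak1 would tie the 2 genes together across mice, and over the 10 KO mice their correlation was -0.146 (Spearman -0.236, permutation p = 0.68), which leaves it undecided. An effect of the targeted allele on its surroundings and loss of a MeCP2 function that R306C keeps are not told apart here.

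For the higher long-gene index of KO whole-cell RNA, the test of transcript GC was chosen after its result was seen, and the tests of transcript length and depth before theirs, though all followed the index itself. Against shorter genes matched on transcript GC the difference was 0.0481, and against those matched on transcript length 0.0438, so neither property accounts for it. Index and log2 total count correlated at -0.134 within genotype (Spearman -0.0361, permutation p = 0.59), which does not decide on depth. GC of the gene span was not tested for want of a genome sequence.

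For the lower choroid plexus and ependyma markers of R306C mice, both tests were chosen after the list call and before their own results were seen. Mean total counts of R306C whole-cell libraries were 5.06 percent above wild type, so smaller libraries do not account for it. If less choroid plexus had entered the R306C samples, a mouse would score alike in its whole-cell and nuclear RNA, and within genotype the scores correlated at 0.278 (Spearman 0.429, permutation p = 0.19, n = 20), between the limits set for either answer. Loss of tissue at dissection could still lie behind these markers.

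Random splits of the same libraries, 100 with the real one, show how many calls arise without genotype, and this test was fixed before the data were seen. Splits within pairs were added once the likeness of mice of 1 number was known. As many genes as in the real split were called in 1 split for KO whole-cell RNA (2767 genes, highest other split 412), 2 for KO nuclear (1748, 1982), 1 for KO chromatin-associated (1579, 171). R306C gave 1, 1 and 1 in whole-cell, nuclear and chromatin-associated RNA (1049, 845 and 707, highest other 5, 561 and 116), and the Dnmt3a cKO 1 (512, 39). Chance is excluded at 5 in 100 for all 7, although 1 random split of KO nuclear libraries called more genes than genotype did. For the wild-type fractions the values were 1 (5496, 4285) and 1 (7776, 1). For differences between fractions 0 genes were called in KO and R306C, and a count of 0 cannot be tested by splits. Allele differences gave 2 in whole-cell (7 genes, highest other 61), 4 in nuclear (1, 1838) and 3 in chromatin-associated RNA (2, 1009), fewer than 5 of 100. The nuclear call is Irak1 and the chromatin-associated calls are Irak1 and Mecp2, which are also among the whole-cell calls. Mecp2 mRNA is lost in KO and not in R306C, so these counts do not show that the alleles differ at other genes. Some splits called many more genes, and what such splits have in common was not tested. Splits within pairs gave 1 for R306C whole-cell RNA (highest other 285) and 1 and 1 for the wild-type fractions (highest other 4292 and 6215). As many lists as in the real split passed in 6, 72 and 57 splits for KO whole-cell, nuclear and chromatin-associated RNA (real 13, 9 and 10, highest other 17, 22 and 24). For R306C they were 37, 68 and 76 (real 10, 7 and 6, highest other 16, 20 and 22) and for the Dnmt3a cKO 10 (real 14, highest other 17). For the number of lists chance cannot be excluded in these comparisons. The wild-type fractions gave 3 (real 22, highest other 23), where chance is excluded, and 18 (real 18, highest other 21), where it is not.

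List by list, which was looked at after, the splits with a p as small were counted out of 100 for each list that passed. KO whole-cell RNA had 1 for genes reported earlier, 1 for neuronal splicing regulators, 3 for long synaptic adhesion genes, 3 for oligodendrocyte precursor markers, 4 for cadherins and protocadherins and 4 for astrocyte markers, with 10 to 62 for the other 7. KO nuclear RNA had 1 for genes reported earlier and 4 for striatum markers, with 9 to 56 for the other 7. KO chromatin-associated RNA had 1 for genes reported earlier, with 6 to 48 for the other 9. Irak1, the neighbour of Mecp2, is a member of the genes reported earlier. Without it camera gave this list adjusted p = 0.0266 in KO whole-cell RNA, and no call in KO nuclear (0.0792) or chromatin-associated RNA (0.3). Splits without Irak1 were not counted. R306C whole-cell RNA had 2 for genes reported earlier, 3 for beta protocadherins, 3 for glutamate receptors and 4 for oligodendrocyte precursor markers, with 5 to 24 for the other 6. R306C nuclear RNA had 6 to 40 for all 7 lists. R306C chromatin-associated RNA had 1 for imprinted genes and 3 for oligodendrocyte precursor markers, with 15 to 45 for the other 4. The Dnmt3a cKO had 1 for GABA receptors, 2 for potassium channels and 2 for neuropeptides, with 6 to 48 for the other 11. The wild-type fractions of the KO cohort had 1 for neuropeptides, 1 for ribosomal protein genes, 1 for mitochondrially encoded genes, 3 for nuclear-retained long non-coding RNAs, 4 for microglia markers and 4 for excitatory neuron markers, with 5 to 49 for the other 16. Those of the R306C cohort had 1 for neuropeptides, 1 for nuclear-retained long non-coding RNAs, 1 for mitochondrially encoded genes and 4 for ribosomal protein genes, with 5 to 48 for the other 14. Chance cannot be excluded for the lists at 5 or more.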

How the results depend on the processing

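Leaving out single libraries or members, GENCODE spans and matching on transcript GC or length were added after results were seen, and the other settings were planned. With replicate number as a block the calls were 4561, 3028 and 2946 in KO whole-cell, nuclear and chromatin-associated RNA and 2814 in R306C whole-cell RNA (16 lists passed). They were 45, 86 and 14 for the allele differences in the 3 fractions. In nuclear RNA 72 were higher and 14 lower with the block, against 0 and 1 without. In chromatin-associated RNA 11 were higher and 3 lower, against 0 and 2 without. The block turned the balance of KO whole-cell calls, with 2420 higher and 2141 lower against 1341 higher and 1426 lower, and gave 1504 higher and 1524 lower in KO nuclear RNA. With 2 surrogate variables the calls were 4704 in KO nuclear, 2776 in KO chromatin-associated, 3159, 1701 and 1563 in the R306C fractions and 1036 in the Dnmt3a cKO, where Cacna1g turned to -0.0332 (adjusted p = 0.854). DESeq2 called 805 in the Dnmt3a cKO and 51 and 11 for the allele differences in nuclear and chromatin-associated RNA, where the limit of mean log2 CPM at 1 gave 2 and 4. The long-gene index of KO whole-cell RNA passed with a limit of 200 kb at 0.0737 (adjusted p = 0.0091), without a filter at 0.0646 (adjusted p = 0.022), as a median at 0.0729 (adjusted p = 0.032) and with the block at 0.0556 (adjusted p = 0.041). It also passed against shorter genes matched on transcript GC at 0.0481 (adjusted p = 0.00049) or transcript length at 0.0438 (adjusted p = 0.0022), and so did that of R306C whole-cell RNA in the last setting at 0.0264 (adjusted p = 0.049). It did not pass with a limit of 50 kb at 0.04 (adjusted p = 0.44), with a mean log2 CPM of at least 1 at 0.0521 (adjusted p = 0.091), matched on mean log2 CPM at 0.05 (adjusted p = 0.15) or with GENCODE spans at 0.0534 (adjusted p = 0.091). Matched on mean log2 CPM the index of KO chromatin-associated RNA was 0.0197 (adjusted p = 0.96). The sign of the index turned, without passing, in KO nuclear RNA matched on mean log2 CPM at -0.00929 (adjusted p = 0.96). So it did in R306C nuclear RNA in that setting at -0.00275 (adjusted p = 0.96) and at 200 kb at -0.00474 (adjusted p = 0.94), and in the Dnmt3a cKO as a median at 0.0137 (adjusted p = 0.8). With an estimated correlation 1 list passed in KO whole-cell RNA, 0 in KO nuclear, 0 in KO chromatin-associated, 0, 0 and 0 in the R306C fractions, 1 in the Dnmt3a cKO, and 0 and 0 in the wild-type fractions. Without Irak1 the genes reported earlier had adjusted p = 0.0266 in KO whole-cell, 0.0792 in KO nuclear and 0.3 in KO chromatin-associated RNA. The block took 3 lists above 0.05, imprinted genes in R306C chromatin-associated RNA (0.0765) and endothelial (0.056) and striatum markers (0.054) in the Dnmt3a cKO. It took 1 list below 0.05 in KO whole-cell, 2 in KO chromatin-associated, 6 in R306C whole-cell RNA, 1 in the Dnmt3a cKO and 4 and 2 in the wild-type fractions of the KO and R306C cohorts, and changed no other list call. Of genes named, it gave a call to Mecp2 in R306C whole-cell RNA (adjusted p = 0.00609) and Dnmt3a in KO chromatin-associated RNA (0.00578) and ended that of Peg3 in the Dnmt3a cKO (0.0549). Each result was set against each of its alternatives. For the 185 gene values printed, 1154 cases held, 7 lost the call (of 4 values), 7 gained one (of 4 values) and 1 turned. For correlations all 63 cases held. For counts of genes 62 held and 18 moved, and for the index 63 held, 7 gained a call and 4 turned. Matching shorter genes on GC of the gene span was planned and not run, since no genome sequence was at hand, and the cause of these moves was not tested.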

Other observations

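Choroid plexus and ependyma markers did not pass as a list in any KO fraction, with adjusted p = 0.18, 0.0804 and 0.537 in whole-cell, nuclear and chromatin-associated RNA. In KO nuclear RNA 4 of 12 choroid plexus and ependyma markers fell (0 up and 4 down adjusted over the list alone, adjusted p = 0.0804, adjusted p = 0.777 with an estimated correlation). The water channel Aqp1 was at -0.91, the folate receptor Folr1 at -0.79 and the thyroid hormone carrier Ttr at -0.61. Markers of inhibitory interneurons rose in 3 and fell in 3 of 14 in KO whole-cell RNA and did not pass as a list (5 up and 3 down adjusted over the list alone, adjusted p = 0.811, adjusted p = 0.871 with an estimated correlation). Among them Pvalb, a calcium buffer of fast-spiking cells, rose by 0.47 in KO and 0.40 in R306C whole-cell RNA while Sst fell by 0.31 in KO.

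Shorter genes called in KO whole-cell RNA were higher in 40.9 percent of cases and longer ones in 72.5 percent, and the same split held in the KO chromatin-associated RNA, with 70.8 percent of long genes called higher. The index that sums this up failed adjustment. Within genotype it followed the first principal component at 0.955 in KO whole-cell, 0.949 in KO nuclear, 0.987, 0.977 and 0.965 in the R306C fractions, against 0.417 in KO chromatin-associated RNA and 0.554 in the Dnmt3a cKO (Spearman 0.896, 0.934, 0.983, 0.968, 0.911, 0.402 and 0.601). Against shorter genes matched on transcript GC or length, settings added after results were seen, the KO whole-cell shift passed at 0.0481 (adjusted p = 0.00049) and 0.0438 (adjusted p = 0.0022), and matched on expression, as planned, it did not at 0.05 (adjusted p = 0.15). Over all settings the shift ran from 0.04 to 0.0737, with a call in 6 of 10 alternatives, so both its size and its call depend on the setting. In R306C whole-cell RNA the index stepped with replicate number in both genotypes. Replicates 1 to 6 lay at 0.805 or less and replicates 7 to 10 at 0.839 or more. The first principal component parted the same replicates. Matching on transcript length cut the standard deviation from 0.0768 to 0.0242 in R306C and from 0.0497 to 0.0187 in wild type. What sets these replicates apart is not stated in the labels and was not tested. A test would prepare RNA several times from each lysate, to part variation of preparation from that of mice.

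Whether MeCP2 acts mainly on transcription stays open. The effect differed between chromatin-associated and nuclear RNA for 0 genes, with or without the mouse as a block, but the blocked test recovered 34 percent of simulated 1.2-fold differences in KO and 66 percent in R306C (98 and 98 percent at 1.5-fold). Recovery on real counts may be lower. Small differences may thus be missed, and effects on RNA in the cytoplasm would leave both fractions alike. Counting intron reads alone in nuclear RNA, and sequencing of nascent RNA from the same mice, would separate initiation from later steps for genes such as Sdk1 and Cacna1g.

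The rise of Irak1 may belong to the targeted Mecp2 allele, given the R306C log2 fold change of -0.0488. Loss of a MeCP2 function that R306C keeps could also lie behind it. Reads spanning the Mecp2 to Irak1 gap, or a knockout made by another design, would tell, and studies that use Irak1 as a readout of MeCP2 loss would need that control.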
